A study of Mus musculus with 3 samples.

How the data were processed

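RNA from the livers of vehicle-treated male Wistar rats was measured on 3 one-colour Agilent arrays, 1 array per sample. Per the labels' protocols, ribosomal RNA was removed and the remaining RNA was amplified and labelled with Cy3 by random priming along the whole transcript. The labels name the samples as replicates 1, 2 and 3 of 1 vehicle group and do not say what the vehicle was. The organism field of the labels says mouse, whereas the strain, the protocol and the title say rat, and the genome build in the array headers is the rat build rn4. The samples are treated here as rat. The labels do not state that the 3 samples came from separate animals, so every SD measures the spread between these samples, which may be technical.

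Each scanner file holds intensity values that were made with Agilent Feature Extraction 11.0.1.1, per the file headers, with background subtraction and no scaling between arrays. Its flags, which are 0 or 1 per spot, mark spots well above background, positive and significant spots, saturated spots and outliers. The deposited table of processed values is on the log2 scale. How it was made is not given in the sources used here. Set against the scanner values, its log2 values correlated with r of at least 0.99998 above a value of 3 on each array, with slopes of 0.996, 0.988 and 1.02 on arrays 1, 2 and 3. Its sorted columns differed by at most 0.0176 above that value, which is the pattern that quantile normalization gives. The column medians were 3.66, 3.66 and 3.66, and the values were not centred per probe. Low values were tied at about 2.32, 2.33 and 2.32, close to log2 of 5. The table listed 38269 of the non-control probes studied here, and 52 others were taken from the scanner files alone.

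All 3 arrays came from 1 slide and 1 scan, so slide and scan date form no batch among them, and array position cannot be told apart from sample. Each array had 41623 non-control spots for 38321 probes. The 75th percentile of the non-control signal was 112.1, 101.7 and 112.8 on arrays 1, 2 and 3, and no non-control spot was saturated. Outlier flags covered 72, 80 and 78 of these spots and those spots were dropped. The number of arrays limits the precision of all values.

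The main setting was log2 of the processed signal minus each array's 75th percentile of it over non-control probes, so that a level of 0 is that percentile. Spots of a probe were averaged. A probe was called above background on an array when over 50% of its spots carried the well-above-background flag, and measured when this held on all 3 arrays and all 3 gave a value. The SD between samples was taken over the 3 levels. Agreement was given as Pearson's r, Spearman's rho and the number of probes over 2-fold apart. These are across probes, which are not independent replicates. Spot error was the SD over the spots of a probe within an array, divided by the square root of their number. Detection of the strands of a region was compared with Fisher's exact test and an exact McNemar test, and neighbouring regions with a one-sided permutation test over 100000 shuffles. The Benjamini-Hochberg adjustment covered these 5 tests. The spread of ultraconserved probes was set against other probes of like level in 20 bins and placed among 10000 random sets. No test between groups was run, because there is 1 group and no contrast.

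The measure of class spread was tested on simulated data for 22214 probes with 200 of them widened. All 20 runs with a 1.5-fold wider SD and all 20 with a 2-fold wider SD were called, and 0 of 20 runs without widening. The test of neighbouring regions called 20 of 20 simulated clustered sets and 0 of 20 random ones over 481 regions. The simulated effects were larger than those seen in the data, so the power at the observed sizes was not tested.

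Before the data were examined, alternatives were fixed. They were quantile normalization, normexp background correction with an offset of 50 followed by either scaling, the deposited values, other filters on dim probes, the percentile over detected probes, another detection flag and leaving out each replicate. The files have no mean-signal column, so normexp was run on the median spot signal and the median local background. Naming rules were fixed too, with at most 2 probes high and 2 low by ID where the files name no genes. The files gave no gene symbols for the 38321 non-control probes. The reference tables used here are for mouse, and 0 of the 43 RefSeq accessions in the files matched them. For that reason 30 gene lists fixed beforehand, and the comparison of long noncoding RNAs with mRNAs, were not run, and probes are given by their IDs. A list of ultraconserved regions named in published work was written after the files were opened and before their values were seen. The analyses of ultraconserved regions, of neighbouring regions and of the array block were added after seeing the data. Probes printed 10 or 30 times and ultraconserved probes with the widest or narrowest spread were also named after their values were seen.

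Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.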

Results

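The series profiled RNA in the livers of vehicle-treated male Wistar rats, an outbred laboratory strain. It holds 3 samples of 1 group, each on its own array, and no treated group. It was used to describe how alike the 3 samples were and which probes gave signal in them. The arrays carried 38321 non-control probes. Of these, 37277 belonged to a numbered catalogue with 1 spot each, and 962 were for ultraconserved regions, which are stretches of genome that are identical in human, mouse and rat. The ultraconserved probes cover both strands of 481 regions, with 3 spots each. Another 50 probes carried outside accessions with 10 spots each, and 32 custom probes had 30 spots each.

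Liver RNA gave signal above background at 62.6%, 60.1% and 64.5% of the probes in samples 1, 2 and 3, or 62.4% ± 2.24 (SD, n = 3). In all 3 samples 22466 probes (58.6%) were above background, 3018 were in some samples only, and 12837 (33.5%) were in none. Of the catalogue probes 22220 (59.6%) were above background in all 3 samples. Of the 481 plus-strand probes of ultraconserved regions 93 (19.3%) were, and of the 481 minus-strand probes 103 (21.4%). Of the 50 probes with accessions and 10 spots 38 were above background in all 3, and of the 32 custom probes 12. All 12 of these were custom probes with an accession. The 20 custom probes without one were never above background in all 3 samples, and 3 of them were in at least 1 sample.

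The 3 samples differed little. Over the 22459 measured probes the median SD between samples was 0.134 log2 units, and 20652 probes (92.0%) lay within 1.5-fold in all 3 samples. The 90th percentile of the SD was 0.286 and the 99th 0.509. Between any 2 samples 200 probes (0.891%) differed over 2-fold and 11 over 4-fold. Pearson's r across probes was 0.9969 for samples 1 and 2, 0.9959 for samples 1 and 3 and 0.9956 for samples 2 and 3. Spearman's rho was 0.9943, 0.9935 and 0.9929. Samples 1 and 2 differed over 2-fold at 100 probes, samples 1 and 3 at 70 and samples 2 and 3 at 99. The median difference was smallest between samples 1 and 2, at 0.11 log2 units against 0.17 and 0.18 for the pairs with sample 3. After quantile normalization these were 0.11, 0.16 and 0.16. Sample 1 lay over 2-fold above both others at 4 probes and below both at 4. For sample 2 these counts were 15 and 19, and for sample 3 they were 21 and 6. The counts were also taken over 22271 probes, without the spots in rows 332 to 354 and columns 69 to 85 of array 3. In that block, chosen after seeing the data, a disturbance may have raised spots. The counts of sample 3 were then 11 and 6, and those of the others were as before. With normexp background correction the median SD fell to 0.0706 and the probes over 2-fold to 11, and over probes above background in at least 1 sample they were 1552. Without sample 3 the median SD was 0.0777 over the 2 others, against 0.125 without sample 1 and 0.122 without sample 2.

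The spread was wider among dim probes. The median SD was 0.222 log2 units in the dimmest 10% of the measured probes and 0.110 in the brightest 10%. Each array also deviated with signal level. Sample 3 lay at a median of 0.05 above the mean of the 3 samples in the dimmest 10% and at -0.10 in the brightest, whereas sample 1 lay at 0.01 and 0.06 and sample 2 at -0.07 and 0.03.

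**Figure D1:**
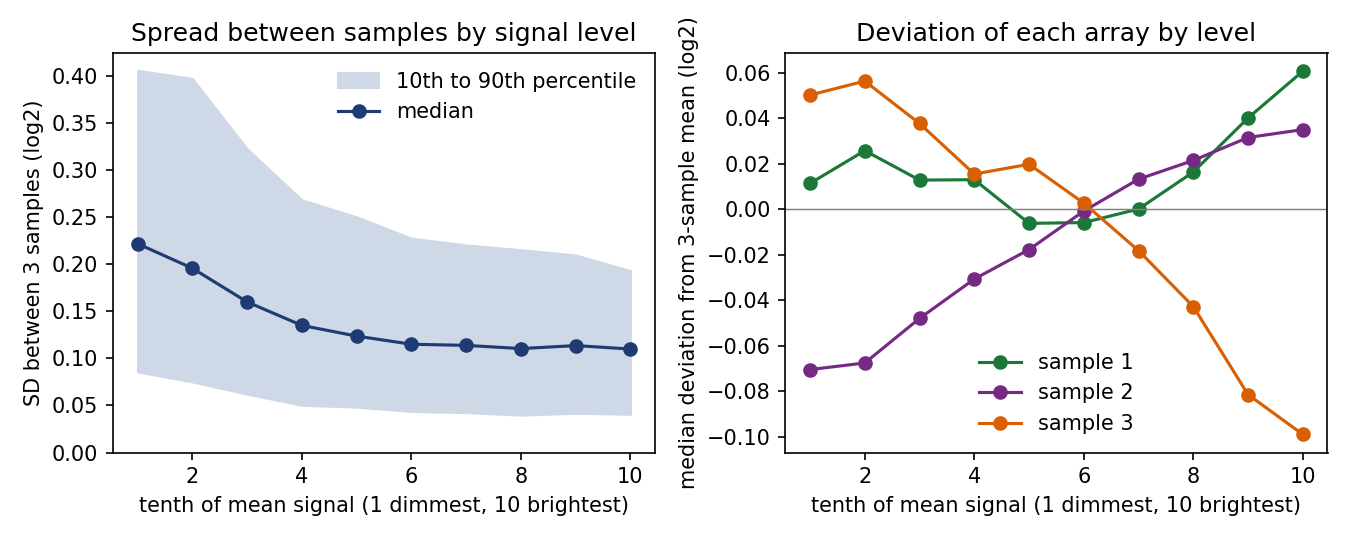
Left, SD between the 3 samples (log2) in 10 equal groups of mean signal, with the median as a line and the 10th to 90th percentile as a band. Right, median deviation of each array from the 3-sample mean (log2) by the same groups. The median SD goes from 0.222 in the dimmest group to 0.110 in the brightest, and the deviation of sample 3 from 0.05 to -0.10.

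Among probes in the upper 75% of signal, the largest differences between samples were at catalogue probes with a single spot. ASRNV20014701 was 46.0-fold higher in sample 3 than in the lowest sample, with levels of -3.21, -3.73 and 1.80 in samples 1, 2 and 3 (SD 3.05, n = 3). ASRNV20010718 was 5.93-fold higher in sample 3 than in the lowest sample (-2.79, -2.44 and -0.22, SD 1.39, n = 3). ASRNV20021923 was lowest in sample 1, 4.35-fold under the highest sample (SD 1.12, n = 3). ASRNV20012720 was lowest in sample 3, 4.31-fold under the highest (SD 1.12, n = 3). Of the 15 probes with the widest range, 5 had 1 sample high and 10 had 1 sample low. The sample that stood low was sample 2 in 6 of those 10. All 3 of these 15 probes that were high in sample 3 lie in a small block of array 3. Among them are ASRNV20014701 and ASRNV20010718. Other spots of that block were also raised. With normexp the SDs of ASRNV20014701, ASRNV20010718, ASRNV20021923 and ASRNV20012720 fell to 1.52, 0.55, 0.48 and 0.54. Without sample 3 the SDs of ASRNV20014701, ASRNV20010718 and ASRNV20012720 were 0.36, 0.25 and 0.28, and without sample 1 that of ASRNV20021923 was 0.33. These single-spot values have no check within an array.

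**Figure D2:**
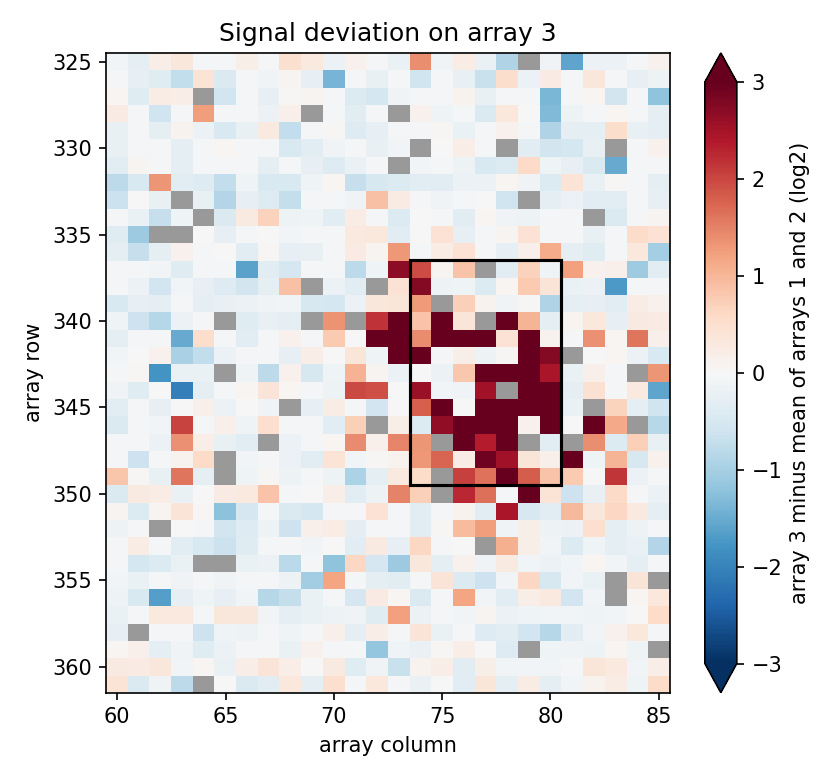
Signal of array 3 minus the mean of arrays 1 and 2 (log2, relative to the median of the array) by array row and column, with colours ending at 3 and -3 and grey where no spot is listed. The box marks rows 337 to 349 and columns 74 to 80, in which 35 of 74 spots other than the widest probes were raised over 2-fold.

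Probes printed many times allow the spread between samples to be set against spot error. The 12 measured custom probes with 30 spots had a median SD between samples of 0.0932 log2 units against a median spot error of 0.0096. The ratio had a median of 9.68 and ranged from 3.56 to 18.3, where spot error alone gives a median of 0.836. All 12 lay above 2 times that median. The probe for NM_001004082.3 had the widest spread of these, an SD of 0.186 with deviations of -0.06, -0.15 and 0.21 in samples 1, 2 and 3. For the 38 measured probes with 10 spots the median SD was 0.0924 and the median ratio 4.48. Of these 36 lay above the median for spot error alone and 31 above 2 times it. NM_022209 had the widest spread among them, an SD of 0.29 and a 1.49-fold range, with levels of -2.74, -2.94 and -3.31 in samples 1, 2 and 3. For the 195 measured probes with 3 spots, those of ultraconserved regions, the median ratio was 1.56 against a median of 0.883 for spot error alone. Of these 148 lay above that median, which many probes exceed by spot error alone, and 86 above 2 times it. After quantile normalization the median SD of the 30-spot probes was 0.0428 and the median ratio 3.83, with a range from 1.26 to 20.9. Then 9 of the 12, rather than all, lay above 2 times the median for spot error alone. The median ratio was then 4.31 for the probes with 10 spots and 1.61 for those with 3 spots.

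**Figure D3:**
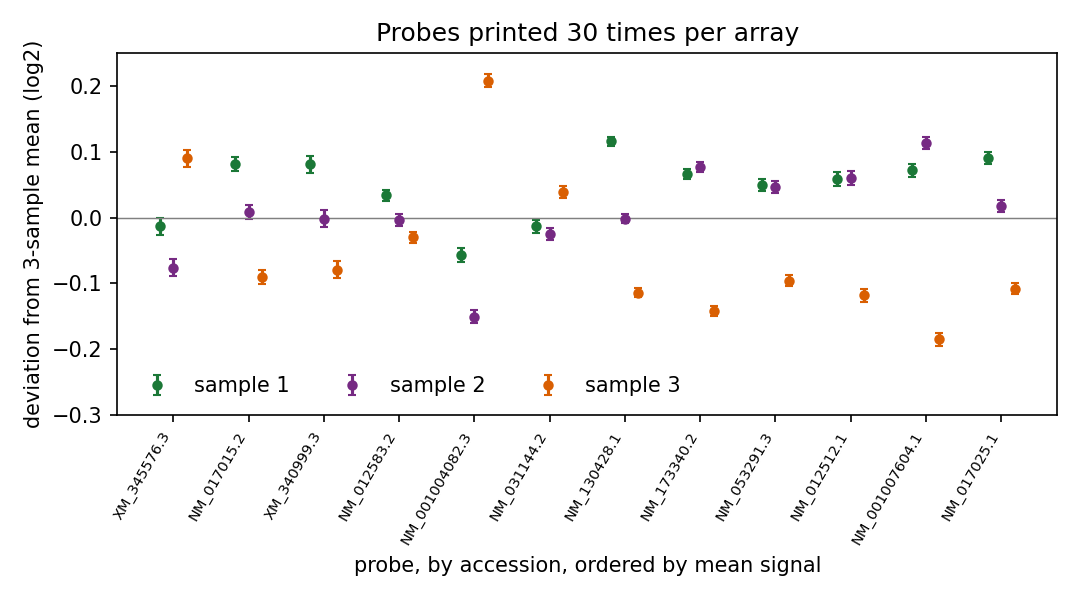
Deviation of each sample from the 3-sample mean (log2) for the 12 measured probes printed 30 times per array, ordered by mean signal and named by accession. Bars show the spot error, with a median of 0.0096, and the SD between samples exceeds the spot error at all 12 probes.

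Signal above background from ultraconserved regions was found in 164 of 481 regions (34.1%) on at least 1 strand in all 3 samples. The plus strand alone was detected in 61 regions, the minus strand alone in 71, both in 32 and neither in 317. In 277 regions neither strand was above background in any sample. Regions with both strands were more frequent than the 19.9 that independence gives (odds ratio 2.34, 95% interval 1.37 to 3.95, Fisher's exact p = 0.00113, adjusted p = 0.00565 over 5 tests). Fisher's test and its interval take regions as independent. Detected regions lay next to each other more often than shuffled ones, so that p may be too small and the interval too narrow. The numbers of regions with the plus or the minus strand alone did not differ beyond chance (exact McNemar p = 0.434, adjusted p = 0.434). With the less strict detection flag 194 plus strands, 182 minus strands and both strands of 95 regions were detected. Either strand was then detected in 281 regions (58.4%), and 89 regions had neither strand in any sample.

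**Figure D4:**
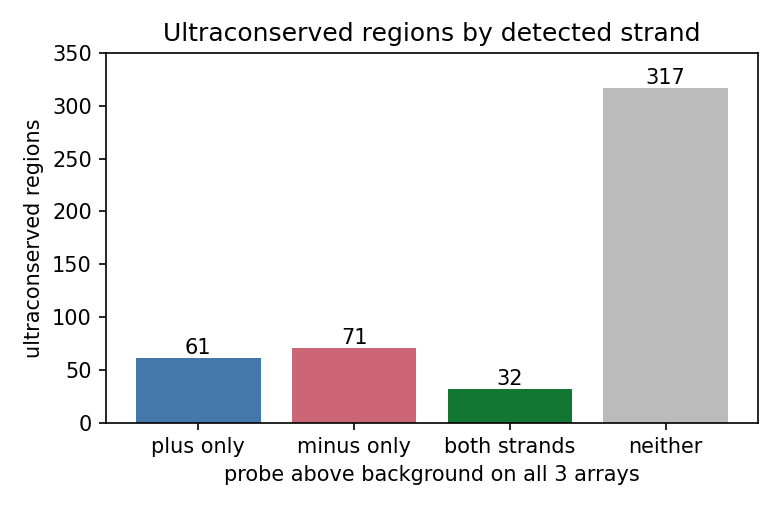
Number of ultraconserved regions by the strand whose probe was above background in all 3 samples. Of the 481 regions 61 had the plus strand only, 71 the minus strand only, 32 both and 317 neither.

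Of the regions looked up because published work names them, uc.475, uc.338 and uc.333 had a strand above background in all 3 samples. uc.475, whose plus strand was at 0.64 ± 0.16 and minus strand at -2.32 ± 0.07 (mean and SD of the level, n = 3), was measured on both strands. uc.338 was measured on the plus strand at -4.06 ± 0.29 (n = 3) and its minus strand was above background in 1 sample. uc.333 was above background on the minus strand in 3 samples, but its value in sample 3 carried an outlier flag, so its level is over 2 samples (-3.74 ± 0.34, n = 2). For uc.372, uc.346 and uc.73 at least 1 strand was above background in 1 or 2 samples, and for uc.160, uc.283 and uc.349 no strand was above background in any.

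The 195 measured ultraconserved probes had a median SD of 0.127 log2 units between samples. Of these 12 differed over 1.5-fold between any 2 samples and 0 over 2-fold. uc.251 on the minus strand (SD 0.48, levels -2.46, -3.43 and -2.87) and uc.226 on the plus strand (SD 0.48) had the widest spread. The SD of uc.251 was 0.29 without sample 2 and 0.064 with normexp. That of uc.226 was 0.018 without sample 1, 0.28 on the deposited values and 0.089 with normexp. Their ratios to spot error were 2.47 and 1.44, and uc.226 lay at a mean level of -4.07, near the lowest measured level of -4.37. These probes were picked as the widest of 195, and their spread was not tested against spot error. uc.367 on the plus strand and uc.409 on the plus strand had the narrowest, with an SD of 0.0063 and 0.0099. Their ratios to spot error, 0.040 and 0.21, lay under 0.883, the median for spot error alone, so they are not distinguished from chance. They also depend on the scaling, as quantile normalization gave 0.12 for uc.367 and 0.035 for uc.409. With 1 spot per probe at like signal level, 182 of the ultraconserved probes could be compared with 22214 catalogue probes. Their SD was 0.0258 wider, at percentile 99.2 of random sets. Whether that difference passed the random sets depended on the setting. It did with quantile normalization (0.0328, percentile 99.9), with 10 bins (0.0282) and without sample 2 (0.0351). It did not where the spot used had itself to be above background (0.0179, percentile 94.3), with normexp (0.0016), without sample 1 (0.0184) or without sample 3 (0.0168).

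Detected regions lay next to each other in number order, which follows the human genome, more often than shuffled ones. There were 67 adjacent pairs of detected regions against a shuffled median of 55 (one-sided permutation p = 0.0121, adjusted p = 0.0302). For the minus strand there were 30 against 22 (one-sided permutation p = 0.0196, adjusted p = 0.0326), and for the plus strand 20 against 18 (one-sided permutation p = 0.295, adjusted p = 0.369). The longest runs were uc.44 to uc.50 with 7 regions, uc.181 to uc.186 with 6 and uc.471 to uc.475 with 5. With the less strict detection flag the one-sided permutation p for either strand was 0.11.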

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

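The test of spot noise and the test of labelling differences were chosen after the result was seen, as were the blocks of array 3, the 30 widest probes behind them, and the joint interval and quantile setting for the strands.

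Of 57 positive control probes, 7 gave signal above background in most spots of all 3 arrays. Control probes are outside the main measurement, and their values here are processed signals on the linear scale, not log2. On that scale the median non-control signal was 11.6, 9.79 and 12.0 on arrays 1, 2 and 3. The mean signals of the 7 over the arrays were 11.8 for (+)E1A_r60_a22, 10.1 for DCP_22_0 and 10.6 for DCP_22_2. They were 7.76 for DCP_22_4, 7.88 for DCP_22_6, 8.39 for DCP_22_7 and 9.27 for ETG10_13482. Negative controls averaged 1.11, 1.08 and 1.06 on arrays 1, 2 and 3.

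The widest probes lay close together on array 3. Of the 30 widest probes 7 fell in rows 337 to 349 and columns 74 to 80, which hold 0.195% of the non-control spots. That block was bounded by those 7 probes. The other 74 spots in it, none of them among the 30, deviated upwards by a median of 0.8623 log2 units from the other arrays, against -0.08 to 0.11 for random sets of spots. Of those 74 spots 35 (47.3%) were raised over 2-fold and 0 lowered, and no spot carried an outlier flag. In rows 332 to 354 and columns 69 to 85 the median deviation was -0.0082, but 18.4% of the spots were raised over 2-fold against 4.47% on the array. A local disturbance of the array surface may account for ASRNV20014701 and ASRNV20010718 in sample 3, and the deviation of neighbouring spots of 0.8623 is what it needs. No biological explanation was tested, as the design gives 1 group.

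The 3 samples differed little, and a question is whether they are repeats of 1 RNA. The ratio of the SD between arrays to spot error had a median of 9.682 over the 12 probes with 30 spots. It does not decide, because spot error within an array leaves out the differences that each labelling and hybridization adds. A trend with signal level as the whole of the excess is argued against for the 12 probes as a set, not for each. After quantile normalization the median ratio was 3.829, above 1.67, which is 2 times the median for spot noise. Of the 12 probes 9 lay above 1.67, and the lowest ratio was 1.26. The bootstrap interval of 2.49 to 5.32 is over probes that share the 3 arrays, so it gives no error for the arrays. Separately labelled portions of 1 RNA, or pooled RNA, stay open. Transcripts with 2 well replicated probes could not exclude them, because a shift of a whole transcript moves both probes together whatever its source. Such transcripts would ask only whether the arrays followed transcript abundance, and there was only 1, NM_017025. Its probe with 10 spots deviated by 0.01, -0.19 and 0.18 in samples 1, 2 and 3 and its probe with 30 spots by 0.09, 0.02 and -0.11, which after quantile normalization were -0.06, -0.20 and 0.26 against 0.014, -0.0027 and -0.011. Differences of labelling and of animals cannot be told apart here.

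Both strands of 32 ultraconserved regions were detected, against 19.9 by chance. A candidate explanation is that 1 RNA gives signal on the probes of both strands. The deviations of the strands between samples correlated with r = -0.01317 (bootstrap interval -0.254 to 0.234, two-sided permutation p = 0.918) over 32 regions, where repeat spots of 1 probe gave 0.537. The correlation minus 50% of that value was -0.282 (joint bootstrap interval of the difference -0.512 to -0.0463). The correlation thus lay under the bound of 50% written beforehand for the explanation. With quantile normalization r was -0.068 (difference from the bound -0.595 to -0.0841). This does not decide, because the bound comes from repeat spots of 1 probe and takes different probes of 1 RNA to deviate alike. The 2 probes of the single transcript NM_017025 did not, and 1 transcript is too little to check it. Both 1 RNA and separate transcripts on the strands stay open, and separate transcripts were not tested.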

How the results depend on the processing

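The alternatives for ultraconserved regions, neighbouring regions and the array block were chosen after seeing the data, while the others were planned. Of 82 alternatives to the main results 58 stayed within a tolerance and 24 did not. The tolerance was the same direction and side of the threshold for a test, 1.5 times the main value for a count, and the SD over the fits that leave out a replicate for the median SD (0.0267) and the lowest r (0.00066). With normexp the median SD was 0.0706, the lowest r 0.9974 and the probes over 2-fold 11, and with normexp and quantile normalization they were 0.0636, 0.9975 and 10. The offset of normexp shrinks differences between dim probes by construction. Over probes above background on at least 1 array, the lowest r was 0.9897 and 1552 probes were over 2-fold, and in the upper 50% of signal 15 were. The cause was not tested further. Leaving out replicate 1, 2 or 3 gave a median SD of 0.125, 0.122 or 0.0777, so fewer samples alone do not explain the last. The lowest r was then 0.9956 to 0.9969 and 70 to 100 probes were over 2-fold. Probes above background were 28355 (74.0%) with the less strict detection flag, against 22466, and 22588 to 23401 when a replicate was left out. Quantile normalization, the deposited values, the percentile over detected probes and leaving out the wider array block kept these 3 measures within the tolerance. The probes over 2-fold were then 184 to 209.

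With the less strict detection flag 194 plus and 182 minus strands were detected and 95 regions had both. The plus strand then led and the exact McNemar p was 0.42, still not past the threshold. The strand association stayed past it in all alternatives (Fisher's exact p 5.35e-05 to 0.00351), and the one-sided permutation p of adjacent pairs rose to 0.11. The cause was not tested. With the mean of 3 spots the spread of ultraconserved probes against catalogue probes was -0.0306, a sign built in by averaging the spots of those probes only, so it decides nothing. The difference was 0.0328 with quantile normalization and 0.0282 with 10 bins. It was 0.0016 with normexp and 0.0179 where the spot used had itself to be above background. Leaving out each replicate gave 0.0168 to 0.0351.

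The SDs of 8 named probes moved by over 1.5 times in 29 of 78 alternatives. With normexp that held for all 4 catalogue probes (1.52, 0.55, 0.48 and 0.54) and all 4 ultraconserved ones. Settings fixed beforehand but not run were those on gene lists, on shifts of lists in single samples, on long noncoding RNAs against mRNAs and on the mean over probes of a gene, since no probe had a gene name. Signal over background limits the dim probes, where the spread is widest.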

Other observations

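The 2 tests in this part had predictions written beforehand, but the analysis of neighbouring regions was itself added after seeing the data. The intervals around the shares were added after the result was seen, and the boundary between ID numbers was chosen after it.

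Detection in the catalogue followed the numbers of the probe IDs. Of the 27000 probes with numbers up to 27000, 68.2% (95% Wilson interval 67.6 to 68.8) were above background in all 3 samples, and of the 10277 after it 37.0% (36.1 to 38.0). The intervals take probes as independent with a common share in each range, and give no error for the arrays. Shares in blocks of 1000 IDs varied widely, so the intervals are too narrow. Up to 27000 the blocks ran from 26.9% (9001 to 10000) to 80.5% (12001 to 13000). Blocks from 5001 to 9000 were at 57.1% to 60.7%, and that from 10001 to 11000 at 56.8%. After 27000 the blocks ran from 32.6% (35001 to 36000) to 47.2% (29001 to 30000). The files do not name what the number ranges hold.

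A hypothesis was that a difference in gain between arrays sets the difference in the share of probes above background. The shares spanned 4.47 percentage points. With 1 common limit on the scaled signal they were 62.6%, 60.9% and 63.5% and spanned 2.527 points. The bootstrap interval of 2.32 to 2.75 is over probes and gives no error for the arrays. Over 2.24 points remained, which is 50% of the span and the bound set by the prediction. Gain as the whole of the span is thus argued against on these arrays. The fall in the span cannot be credited to gain, because a common limit also replaces the limit set by each array's own background.

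A second hypothesis was that neighbouring ultraconserved regions share a transcript or its neighbourhood. The 67 adjacent pairs of detected regions against a shuffled 55 are what it predicts. That prediction restates the pattern it was to explain and was tested on the data it came from, so it decides nothing. The p of 0.11 with the less strict flag, and that of the plus strand alone, are no evidence for it.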
